A study of Chlamydomonas reinhardtii with 12 samples.

How the data were processed

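Total RNA of 12 samples of Chlamydomonas reinhardtii, 6 of the parental line labelled CC-3403 and 6 of phytoene desaturase knockouts, was made into CEL-Seq libraries, per the labels' protocols. In this method samples are barcoded at reverse transcription, pooled and amplified by in vitro transcription, and reads come from transcript 3' ends. Per the labels' protocols, the authors aligned the second read to the 281_v5.6 transcriptome with BWA MEM, discarded reads that mapped to several places and counted with the MapAndGo script. The submitters' processing notes also name edgeR, without a version. Whether unique molecular identifiers were collapsed is not given in the sources used here. The deposited values are raw counts per gene identifier, with 17744 identifiers in 12 columns and 0 columns left unmapped. Discarding reads with several places in a transcriptome can remove reads of genes with several transcripts or near-identical copies, so members of the LHCBM and RBCS families are uncertain.

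Each column was given to its sample by its title. The titles of WT libraries 1 to 3 (X3404VE) carry another strain number than the labelled line CC-3403, which the sources do not explain. The RefSeq gene table of assembly v5.5 matched 17742 identifiers by locus tag but gives no gene symbols, and the file gives none. Symbols in parentheses therefore come from lists of Cre identifiers written from general knowledge before the data were examined, and this pairing could not be checked here. Of 25 lists, 19 had identifiers and 6 that needed symbols or product names (among them ribosomal, flagellar, histone, and gamete and zygote genes) could not be matched, so no sexual-stage marker was tested. Of 169 list identifiers 167 were in the file and 131 were tested in the 12-library fit. In the light-harvesting list 19 of 21 identifiers lay in the top 5% of WT expression, in the photosystem list 19 of 19 and in the Calvin-Benson list 12 of 14. RefSeq transcripts per identifier were counted from the same table, in which 1531 have 2 or more, and its assembly differs from the one the authors used.

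Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr by genotype, TMM factors, estimateDisp, glmQLFit and glmQLFTest, two-sided, and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the root of F. The 12-library fit had genotype alone. A fit with 4 groups by title gave E10 against A2 and D2, the 2 parental title sets against each other, and the interaction. A2 and D2 against WT 4 to 6 (5 libraries) and E10 against WT 1 to 3 (7 libraries) were also fitted separately. Lists with 5 or more tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, and with fry. The share of each library's counts taken by a list was compared with an exact permutation of group means over 924 arrangements, or 350 within title sets. Alternatives included DESeq2 1.42.0, limma-voom, RLE and no scaling factors, other filters, a replicate block, title set as a factor, single lines, E10 summed, and each library left out. DESeq2 gave no adjusted p for 673 of 4915 identifiers. Python 3.11.15 with numpy, scipy, pandas and matplotlib computed shares, intervals and plots.

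The genes named were fixed by rule before the data were examined: PDS1, up to 3 members of each list with the smallest p in the 12-library fit, members of the carotenoid, MEP, tetrapyrrole and arginine lists, and 9 further genes; genes outside it are marked or belong to calls of the line and title-set contrasts. No identifier passed in the 12-library fit, so none was named for its fold change.

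The test was run on simulated counts with 200 changed genes in each of 2 comparisons. For A2 and D2 against WT 4 to 6 the test recovered 42.5% of 16-fold and 15% of 8-fold changes and called 4 of 7842 unchanged identifiers. In the 12-library comparison it called 13 of 4715 unchanged identifiers. Recovered changes at 16-, 8- and 4-fold numbered 17, 6 and 2 in the former and 33, 15 and 3 in the latter. Of recovered and unchanged identifiers called, the unchanged ones were thus more than the nominal 5% in both. A 95% Wilson interval is given for shares in 1 library, an exact Clopper-Pearson interval for shares of identifiers, and a Poisson interval or a floor of 3 counts for low counts. Libraries of a group were compared by chi-square per degree of freedom over identifiers with 20 or more counts in a pair, and the lowest value of 3.95, for PDSKO 3 and 4, showed no library deposited more than once.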

Results

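Transcript 3' ends were counted in 12 libraries of the green alga Chlamydomonas reinhardtii grown in liquid culture for 4 weeks in darkness at 25 °C. The 6 WT libraries came from the parental line, an arginine-requiring strain grown in acetate medium with 10 µg/mL arginine. The 6 PDSKO libraries came from transformants in which phytoene desaturase, the enzyme that desaturates phytoene early in carotenoid synthesis, was targeted with Cas9 ribonucleoprotein. PDSKO libraries 1 to 4 were of line E10, library 5 of line A2 and library 6 of line D2. The knockout cells were grown without arginine and were sorted by flow cytometry, so medium, sorting and the introduced plasmid went with genotype. The libraries also fell into 2 sets by their titles: WT 1 to 3 with the E10 libraries, called the first title set here, and WT 4 to 6 with A2 and D2, called the second. Total counts ran from 1393032 to 35992976 in WT and from 6279 to 475103 in PDSKO, and 11649 to 14851 and 1308 to 8526 identifiers were detected. A single count stood for 0.0278 CPM (counts per 1000000 counts) in WT 2 and for 159 CPM in PDSKO 2. Labels call the 6 parental samples independent, and nothing says whether libraries of a line came from separate cultures, so p-values measure the spread between these samples. Gene symbols in parentheses come from lists written before the data were examined, and their pairing with the identifiers could not be checked here.

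**Figure D1:**
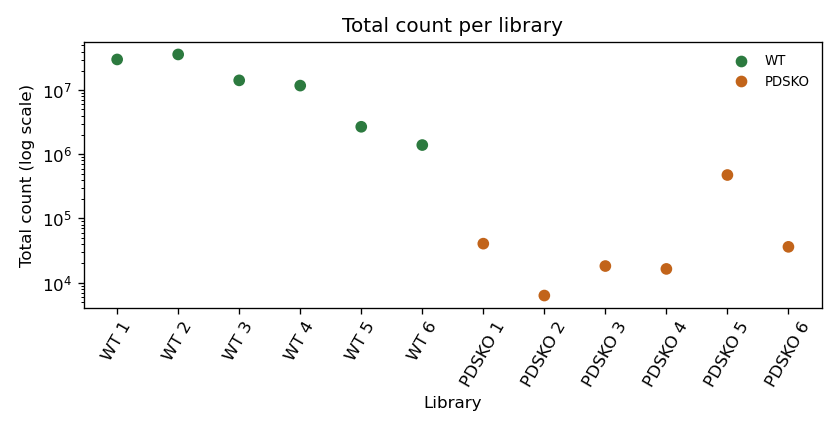
Total count of each of the 12 libraries on a log scale, with WT in green and PDSKO in orange. The highest PDSKO library, of line A2, held 475103 counts and the lowest WT library 1393032.

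The targeted gene, Cre12.g509650 (PDS1), was counted in every WT library and in 2 of the 6 PDSKO libraries. Its level was 61.7 ± 31.2 CPM (SD, n = 6) in WT, with single libraries between 21.6 and 113 CPM. A2 had 0 of 475103 counts, which allows up to 6.31 CPM, and D2 had 0 of 36062, which allows up to 83.2 CPM. Over A2 and D2 together the floor of 3 counts was 5.87 CPM, so the pooled level, set mostly by A2, was at least 8.18-fold lower than the 48.0 ± 26.7 CPM (SD, n = 3) of WT 4 to 6. The edgeR test of these 5 libraries gave an adjusted p of 0.0279, and the call ended without WT 4 (0.0970), WT 5 (0.0912), WT 6 (0.0582) or A2 (0.200). Without Cre07.g323800, which took 43.3% of the A2 counts (Wilson 95% interval 43.1 to 43.4%), the bound was 5.04-fold. The 4 E10 libraries held 4 counts of 81142 together, or 49.3 CPM with a Poisson 95% interval of 13.4 to 126 CPM, against 75.4 ± 34.0 CPM (SD, n = 3) in WT 1 to 3, so no loss was detectable at this depth in E10. Across all 12 libraries the log2 fold change was -2.03 ± 1.01 (SE), with an edgeR adjusted p of 0.256 (0.0279 to 0.643 over 33 alternatives). The position of the edit in the gene is not given in the sources used here. An edit that leaves the transcript's 3' end in place need not lower this count. Intervals and floors cover counting error only.

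The comparison of PDSKO with WT asks which transcripts differ when phytoene desaturase is knocked out in darkness. Transcripts of the photosynthetic apparatus were lower on average in PDSKO, but no identifier passed the test. The 19 tested light-harvesting identifiers, encoding the chlorophyll-binding antenna proteins, all had negative log2 fold changes, with a median of -1.74. The 19 photosystem, cytochrome b6f and electron transport identifiers (median -1.40) and the 13 Calvin-Benson cycle identifiers (median -1.18) were negative throughout as well, against a median of -0.38 over all 4915 identifiers tested. Members of a list moved together (estimated correlation 0.646, 0.597 and 0.194 in this order), so the common signs are not separate observations. With RLE scaling the median of all identifiers moved to 0.29 and 9 of the 13 Calvin-Benson identifiers stayed negative, and with library totals alone 10 did. With both of these scalings all light-harvesting and photosystem identifiers stayed negative. Among the antenna proteins the smallest p-values were those of Cre12.g508750 (LHCA2), with a log2 fold change of -2.61 ± 0.83 (SE), and Cre03.g156900 (LHCBM5), with -3.46. In carbon fixation they were those of Cre08.g380250 (CP12), a regulator of the Calvin-Benson cycle, with -1.81 ± 0.54, and of Cre02.g120100 (RBCS1), a Rubisco small subunit, with -2.72 ± 0.82. These 4 passed when adjusted over the list alone, with adjusted p from 0.0172 to 0.0395, and had edgeR adjusted p from 0.0882 to 0.0968 over all identifiers. Adjusted over the list alone 4 others passed as well, all lower: Cre09.g396650 (PAT1) and the hydrogenase Cre09.g396600 (HYDA2) of the fermentation list, Cre09.g416050 (AGS1) of arginine synthesis, and Cre03.g207900 (CYCA1), an A-type cyclin at 0 counts in all 6 PDSKO libraries and at least 16.5-fold lower by their pooled floor, which is set mostly by A2. AGS1 was the 1 tested member of its list, so its p was not adjusted there. The CYCA1 bound uses the mean of all WT libraries, 83.6 CPM, where WT 4 to 6 had 145 CPM. The zeros of E10 alone allow up to 37.0 CPM, above the 14.6 CPM of the lowest WT library.

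The other lists had no member past the threshold over all identifiers. Median log2 fold changes were -0.72 for 6 carotenoid synthesis identifiers, -0.76 for 6 of the plastid isoprenoid precursor pathway (MEP), -0.66 for 18 of tetrapyrrole and chlorophyll synthesis, -0.89 for 7 of acetate use, -1.61 for 9 of fermentation and -0.05 for 10 chaperones. Cre02.g095092 (PSY1), the phytoene synthase that makes the substrate of the targeted enzyme, had a log2 fold change of 1.67 ± 0.74 (SE, edgeR adjusted p = 0.196). That value rests on PDSKO 3, at 939 CPM where the other PDSKO libraries had 0 to 184, and was 0.53 without it. The small heat shock protein Cre14.g617450 (HSP22E) had 2.26 ± 0.88 (adjusted p = 0.145) and Cre06.g282800 (ICL1), isocitrate lyase of the glyoxylate cycle, -0.89 ± 0.53 (adjusted p = 0.341). HSP22E was at 1162.5 CPM in PDSKO 1 and 1137 in D2 against 0 to 166 in the other PDSKO libraries, and had 1.37 without PDSKO 1 and 1.19 without D2. ICL1 had -1.43 without PDSKO 3 and -0.42 without WT 3. No identifier of the photoprotection list had enough counts to be tested.

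edgeR called 0 of 4915 identifiers at an adjusted p under 0.05 and had 1006 at an unadjusted p under 0.05. DESeq2 called 413 of them, 372 higher and 41 lower, limma-voom 0, and edgeR with RLE scaling 164, 151 higher and 13 lower. Leaving out PDSKO 1 alone raised the edgeR count to 632 of 6777 tested, with 68 higher and 564 lower, among them 13 of 19 light-harvesting, 9 of 19 photosystem and 6 of 14 Calvin-Benson identifiers, all lower. The direction of the called identifiers thus depended on the setting. Without WT 2 and WT 3, 11 identifiers were called, all lower. In simulated counts of these depths the test recovered 82.5% of 16-fold changes, 37.5% of 8-fold changes and 7.5% of 4-fold changes, so most changes below 8-fold were not detectable at this depth.

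No gene list passed the camera test with its preset correlation, nor with an estimated one. In 9 of the 11 lists tested the camera direction was up while the median was negative, among them light-harvesting (adjusted p = 0.960), photosystems (0.873) and the Calvin-Benson cycle (0.352). Camera ran on log-CPM values and compares a list with the other identifiers, and the cause of these opposite signs was not tested. Camera on edgeR's z-scores, added after seeing the data, put 4 lists lower: light-harvesting (adjusted p = 6.92e-05), photosystems and electron transport (3.13e-05), the Calvin-Benson cycle (0.00481) and fermentation and hydrogen metabolism (0.0156). With an estimated correlation none of these 4 held (adjusted p = 0.584, 0.584, 0.389 and 0.366).

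The light-harvesting share of all counts differed between groups by less than its spread within WT. It was 6.62 ± 5.22% in WT and 1.90 ± 3.12% in PDSKO (SD, n = 6 each), a difference with an exact two-sided permutation p of 0.121 (adjusted p = 0.315 over 13 lists). Permuting within the title sets gave an exact p of 0.0914 (adjusted p = 0.170). The permutations of shares treat the 6 PDSKO libraries as separate units, though 4 of them were of line E10. WT 1 stood at 13.6% and WT 4, 5 and 6 at 9.22%, 8.33% and 7.80%, whereas WT 2 and WT 3 stood at 0.427% and 0.391%. In E10 the libraries stood at 8.17%, 0.207%, 0.447% and 0.649%, in A2 at 0.218% (Wilson 95% interval 0.205 to 0.231%) and in D2 at 1.72% (1.59 to 1.86%). The Calvin-Benson share was 3.95 ± 0.947% in WT and 2.32 ± 1.28% in PDSKO (exact permutation p = 0.0238, adjusted p = 0.155, n = 6 each), and permuting only within the title sets gave an exact p of 0.0114 (adjusted p = 0.0743). The photosystem share was 3.86 ± 2.01% in WT and 1.84 ± 1.42% in PDSKO (exact permutation p = 0.0801, adjusted p = 0.288, n = 6 each), with an exact p of 0.0657 (adjusted p = 0.170) within the title sets.

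**Figure D2:**
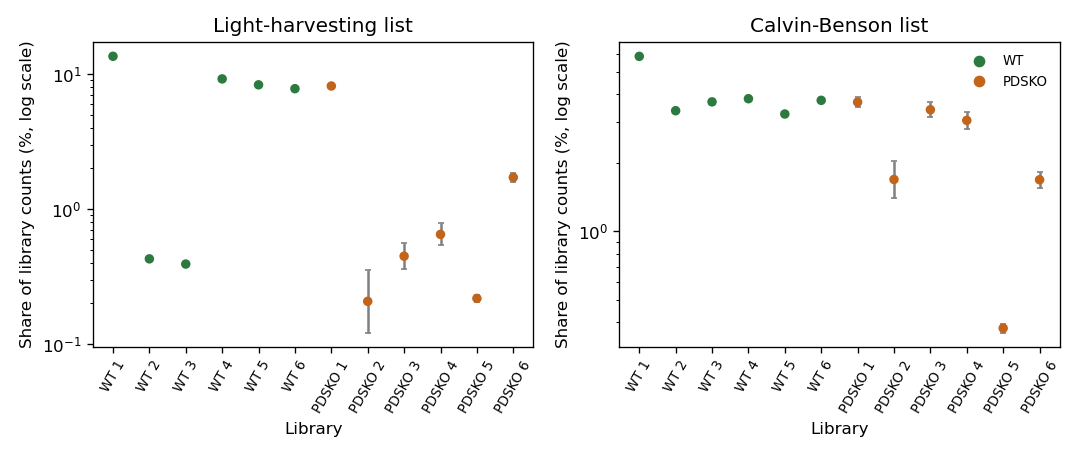
Share of each library's counts taken by the light-harvesting and Calvin-Benson lists, on log scales, with WT in green, PDSKO in orange and Wilson 95% intervals as bars. The light-harvesting share of WT 2 and WT 3 lay at 0.427% and 0.391%, within the range of the PDSKO libraries, and that of PDSKO 1 at 8.17%, within the range of the other WT libraries.

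Lines A2 and D2 were set against WT 4 to 6, the parental libraries of their title set. Antenna transcripts fell: 16 of 20 light-harvesting identifiers were lower and none was higher, with a median log2 fold change of -3.75, or -3.54 with the 1 identifier at 0 in both libraries set to its bound. Cre03.g156900 (LHCBM5) had a log2 fold change of -5.64 ± 0.92 (SE), Cre12.g508750 (LHCA2) of -3.89 ± 0.81 and Cre17.g720250 (LHCB4), a minor antenna protein of photosystem II, of -2.79 ± 0.66, with edgeR adjusted p of 0.00280, 0.0117 and 0.0186. Of the photosystem and electron transport identifiers 7 of 19 fell, among them Cre12.g486300 (PSAL1) with a log2 fold change of -4.21 ± 0.97 and Cre06.g261000 (PSBR1) with -2.88 ± 0.70. Of the Calvin-Benson identifiers 6 of 14 fell, with -3.79 ± 0.75 for Cre02.g120100 (RBCS1), -3.38 ± 0.68 for Cre08.g380250 (CP12) and -2.53 ± 0.65 for Cre02.g120150 (RBCS2). Adjusted over the list alone, 19, 13 and 9 members of the 3 lists fell. The LHCBM and RBCS genes have near-identical copies, and reads that mapped to several were discarded by the authors. All members of the 3 lists were negative with TMM scaling, and 19 of 20, 19 of 19 and 12 of 14 with RLE scaling, which moved the median of all identifiers from -0.92 to -0.42. Camera put the light-harvesting (adjusted p = 1.02e-04) and photosystem lists (0.0375) lower, and neither held with an estimated correlation (camera adjusted p = 0.462 for each). The estimate was 0.324 for light-harvesting, so its common sign is not 20 separate observations. For photosystems it was 0.00845, below the preset 0.01, so correlation among members does not account for the loss of that call. The rotation test fry put all 11 tested lists lower (adjusted p 0.000896 to 0.0445), which does not set these lists apart, as fry does not compare a list with other genes. The carotenoid and chaperone lists had a camera direction of up with negative medians. As a share of counts, the light-harvesting list took 8.45 ± 0.716% in WT 4 to 6 (SD, n = 3), 38.8 times that of A2 and 4.92 times that of D2. The Calvin-Benson list took 3.61 ± 0.298%, 9.56 times that of A2 and 2.14 times that of D2. With Cre07.g323800, which took 43.3% of the A2 counts (Wilson 95% interval 43.1 to 43.4%), left out of the totals, the ratios to A2 were 22.9 and 5.65. A permutation of 2 against 3 libraries cannot give an exact p below 0.1.

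**Figure D3:**
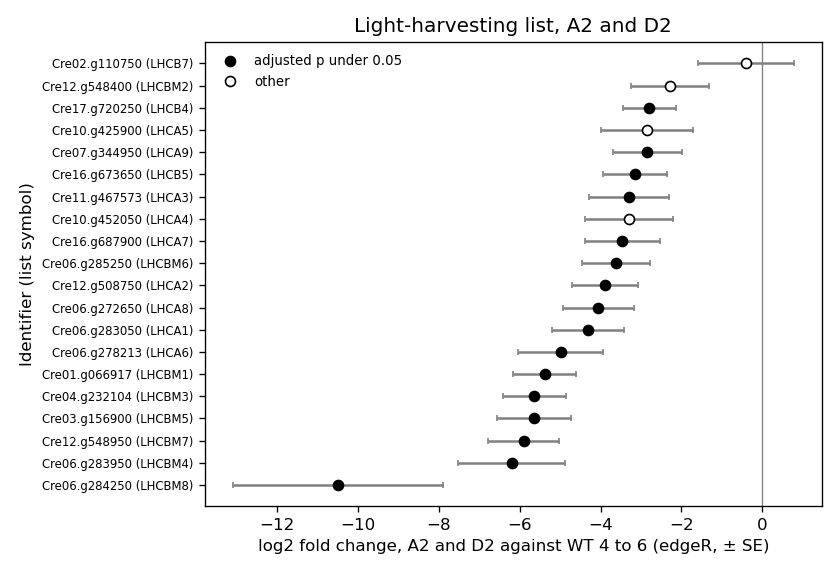
log2 fold changes (± SE, edgeR) of the 20 tested light-harvesting identifiers in A2 and D2 against WT 4 to 6, with filled points for adjusted p under 0.05. All 20 lay below 0 (19 of 20 with RLE scaling) and 16 passed; the lowest point, Cre06.g284250 (LHCBM8), had 0 counts in both lines, and its fitted value depends on the prior count.

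In the other lists of the A2 and D2 comparison single members fell and none rose past the threshold over all identifiers. Cre09.g416050 (AGS1), argininosuccinate synthase of arginine synthesis, had a log2 fold change of -6.54 ± 1.43 (SE, edgeR adjusted p = 0.0141), in cells grown without the arginine that the WT cells received. In the cell cycle list Cre03.g207900 (CYCA1) was at 0 in A2 and D2, at least 24.7-fold lower than the 145 ± 51.2 CPM (SD, n = 3) of WT 4 to 6, and Cre08.g372550 (CDKB1), also at 0, was at least 5.70-fold lower. Cre02.g087700 (APX1), an ascorbate peroxidase of the antioxidant list and at 0 as well, was at least 14.9-fold lower, and Cre17.g746997 (ADH1), the alcohol and aldehyde dehydrogenase of the fermentation list, had a log2 fold change of -4.50 ± 1.00 (edgeR adjusted p = 0.0154). Besides PDS1, 1 of 8 identifiers fell in the MEP list (Cre02.g145050, CMK1, at 0 in both lines and at least 4.38-fold lower), 1 of 20 in tetrapyrrole and chlorophyll synthesis (Cre01.g043350, CAO1, -5.41 ± 1.39), 2 of 9 in fermentation and 1 of 7 in acetate use. These bounds use the floor over both libraries and rest on A2, since D2 alone allows up to 83.2 CPM. Without Cre07.g323800 they were 15.3-fold for CYCA1 (Cre03.g207900), 3.52-fold for CDKB1 (Cre08.g372550), 9.26-fold for APX1 (Cre02.g087700) and 2.72-fold for CMK1 (Cre02.g145050). None passed among 6 identifiers of the carbon concentrating mechanism, 14 chaperones, 3 of nitrogen assimilation, 2 of autophagy, 2 of plastoquinone and plastid terminal oxidase, 1 of mitochondrial respiration and 1 of the eyespot list. Among those that did not pass, Cre02.g095092 (PSY1) had a log2 fold change of 1.71 ± 0.82 (edgeR adjusted p = 0.150), Cre14.g617450 (HSP22E) of 2.56 ± 1.06 (adjusted p = 0.104) and Cre06.g282800 (ICL1) of -2.03 ± 0.69 (adjusted p = 0.0610). The positive value of HSP22E rests on D2, as it was -1.37 ± 0.81 without D2 and 3.71 ± 0.57 without A2 (called, adjusted p = 0.000556). PSY1 had 2.80 without WT 4, and ICL1 had -1.33 without WT 4 and -2.63 without D2 (called, adjusted p = 0.00443).

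Over all identifiers, edgeR called 874 of 8042 in A2 and D2 against WT 4 to 6, 272 higher and 602 lower, and 300 of the lower ones were at 0 in both lines. In simulated counts of this comparison 4 unchanged identifiers were called beside 17, 6 and 2 recovered at 16-, 8- and 4-fold. That is a larger part of the calls than the adjustment is meant to allow. RLE scaling called 780, with 438 higher and 342 lower, among them 13 light-harvesting, 4 photosystem and 3 Calvin-Benson members, all lower. With library totals alone 512 were called, 203 higher and 309 lower, with 7, 2 and 3 members of these lists lower, and with Cre07.g323800 left out 980, with 14, 4 and 6. The counts depended on single libraries: 13 without WT 4, 71 without WT 5, 127 without WT 6 and 2486 without D2, with 1, 4, 7 and 19 light-harvesting members called. Photosystem members called were 0 without WT 4 or WT 5, 2 without WT 6, 10 without A2 and 17 without D2. Calvin-Benson members called were 0 without any of the 3 WT libraries and 10 without D2. Without A2 or D2 a single knockout library is left, which the fit assumes to vary as the WT libraries do. In the fit of all 12 libraries in 4 groups the same contrast called 625 of 4915 identifiers, 367 higher and 258 lower, with 0 of 19 light-harvesting, 1 of 19 photosystem and 2 of 13 Calvin-Benson members lower. HSP22E (Cre14.g617450, 3.51 ± 1.17, edgeR adjusted p = 0.0453) and the acetyl-CoA synthetase ACS2 (Cre01.g055408, 3.43 ± 0.91, adjusted p = 0.0159) passed there. Without D2 neither did, as HSP22E was below 0 and ACS2 had 0.74 ± 0.86. The call of ACS2 (Cre01.g055408) also ended without WT 5 or WT 6, and that of HSP22E (Cre14.g617450) held only without PDSKO 1, WT 1 or WT 3.

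Line E10 was set against WT 1 to 3, the parental libraries of its own title set. No identifier passed the test. All 7 light-harvesting identifiers tested (median log2 fold change -0.91) and all 15 of the photosystem list (median -0.55) had negative values, with each of the 4 scalings tried. The members of each list moved together (estimated correlation 0.777 and 0.806), so the common sign is not 7 or 15 separate observations. In light-harvesting share WT 1 stood at 13.6% and WT 2 and 3 at 0.427% and 0.391%. PDSKO 1 stood at 8.17%, PDSKO 2 at 0.207%, and PDSKO 3 and 4 at 0.447% and 0.649%, above WT 2 and 3. Camera called none of the 4 lists with 5 or more tested members. On z-scores it put the photosystem list lower (adjusted p = 0.0390), which did not hold with an estimated correlation (adjusted p = 0.714). Only 1 carotenoid identifier was tested in these 7 libraries. The light-harvesting share was 2.37 ± 3.87% in E10 (SD, n = 4) and 4.79 ± 7.60% in WT 1 to 3 (SD, n = 3), and the Calvin-Benson share 2.96 ± 0.885% and 4.30 ± 1.34%. edgeR called 0 of 449 identifiers, with 6 at an unadjusted p under 0.05, and 0 of 4915 in the 4-group fit, with 505 at an unadjusted p under 0.05. With 81142 counts over the 4 E10 libraries, only abundant transcripts could be tested.

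E10 was also compared with A2 and D2, to see whether the lines differ. Among the listed genes E10 was lower in Cre12.g530650 (GLN2), a glutamine synthetase, with a log2 difference of -7.23 ± 1.17 (SE). It was also lower in Cre03.g158000 (GSA1), which acts early in tetrapyrrole synthesis (-4.37, edgeR adjusted p = 0.0253), in the catalase Cre09.g417150 (CAT1, -2.87 ± 0.88) and in Cre01.g055408 (ACS2, -2.83 ± 0.85). Of these 4 only GLN2 passed with each library left out, and without PDSKO 4 no E10 count of it remained. Without D2 the difference was -0.88 ± 1.40 for GSA1 and -0.47 ± 0.87 for ACS2, and without A2 it was 0.07 ± 1.03 for CAT1. The call of GSA1 also ended without PDSKO 2, PDSKO 3, PDSKO 4, WT 5 or WT 6, that of ACS2 held only without A2 or WT 1, and that of CAT1 only without D2. The Calvin-Benson identifier Cre01.g029300 (TPIC1), at 0 counts in A2 and D2 and at 0 to 4 in each E10 library, was higher (adjusted p = 0.0497), a call that held only without D2, WT 1, WT 2 or WT 3. CAT1 and TPIC1 were named after their values were seen. No light-harvesting or photosystem identifier passed, and their median log2 differences were 1.29 and 0.51. In all, edgeR called 387 of 4915 identifiers, 60 higher and 327 lower in E10, and 24 of 377 in the PDSKO libraries alone. Leaving out PDSKO 1, PDSKO 3, A2 or D2 gave 181, 207, 147 and 646, and DESeq2 called 592. The lines also lie in different title sets, which differ in the share of counts on identifiers with several annotated transcripts, and GLN2 is such an identifier. Such identifiers were 15 of the 4915 tested and 10 of the 387 calls, and leaving them out gave 383 calls. These values argue against the share difference as the source of most calls.

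The parental libraries of the 2 title sets were compared to measure how far libraries of 1 genotype differ. GLN2 (Cre12.g530650) was at 1.62 to 2.39 CPM in WT 1 to 3 and at 1365 to 1664 CPM in WT 4 to 6, a log2 difference of -9.97 ± 1.12 (SE, edgeR adjusted p = 1.6e-06). Cre03.g207900 (CYCA1) was lower in WT 1 to 3, with a log2 difference of -3.11 ± 0.72, and no other listed gene passed. edgeR called 91 of 4915 identifiers, 43 higher and 48 lower in WT 1 to 3, and 1451 of 13040 when the WT libraries were fitted alone, 237 higher and 1214 lower. Leaving out WT 1, WT 5 or WT 6 changed the 91 to 475, 13 and 21, and DESeq2 called 586. Of the 91, 9 have several annotated transcripts, and leaving out all such identifiers gave 71 calls. Identifiers with 2 or more annotated transcripts took 0.0514 to 0.0719% of the counts in WT 1 to 3 and 0.0159 to 0.109% in E10, against 8.70 to 8.79% in WT 4 to 6, 7.04% in A2 and 11.2% in D2. GLN2 has 2 annotated transcripts, as has Cre05.g234550 (FBA3), a fructose-bisphosphate aldolase chosen after its values were seen, which had 0 counts in all 7 libraries of the first set and 907 to 1945 CPM in WT 4 to 6.

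**Figure D4:**
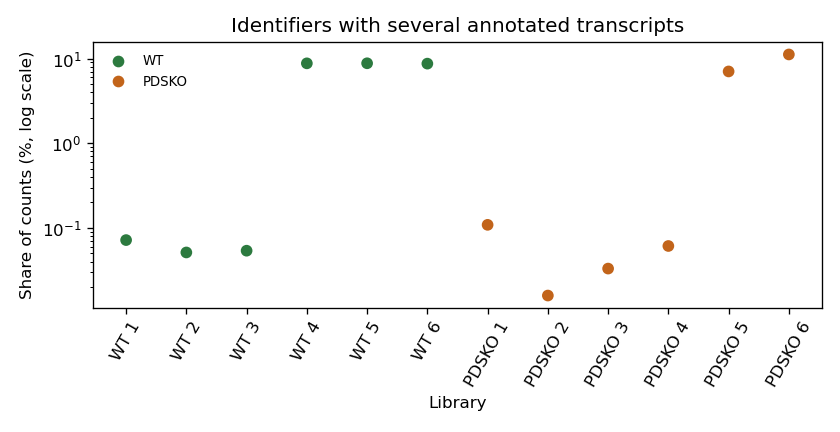
Share of each library's counts on identifiers with 2 or more annotated transcripts, on a log scale, with WT in green and PDSKO in orange. The 7 libraries of the first title set lie at 0.109% or below and the 5 of the second at 7.04% or above.

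Whether the knockout difference itself differed between the lines was tested as an interaction, with each line set against the parental libraries of its own title set. edgeR called 3 of 4915 identifiers, named here after their values were seen: Cre11.g477550 with a log2 difference of -8.94 ± 1.79 (SE), Cre17.g719900 with -7.08 ± 1.44 and Cre14.g609926 with -6.68 ± 1.35. The reference pairs no gene name with them. No listed gene passed, and for PDS1 the adjusted p was 0.211. RLE scaling called 0 identifiers, and leaving out single libraries gave between 0 and 243 (243 without D2, 194 without WT 1, 106 without A2).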

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

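The tests of explanations in this part were chosen after the results they address were seen. Of 32 groups of 6 libraries, 6 had a library far from the others. The cut-off gives about 1 in 20 groups for normal values. These groups are unlogged totals, CPM and shares of the same 12 libraries, so 6 of 32 cannot be set against that rate.

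In PDSKO the library of line A2 stood apart with a total count of 475103, and Cre07.g323800 took 43.3% of its counts (Wilson 95% interval 43.1 to 43.4%) against 0.260 to 4.38% in the other PDSKO libraries. Library 1 of E10 stood apart with a light-harvesting share of 8.17% and a photosystem share of 4.56%, against at most 1.72% and 2.05% in the other PDSKO libraries. WT 1 was highest in the Calvin-Benson share, at 5.84%, and in the chaperone share, at 0.305%. The knockout difference of the lines differed by the interaction test for Cre11.g477550 (-8.94), Cre14.g609926 (-6.68) and Cre17.g719900 (-7.08, log2); D2 held 1192, 2080 and 1470 CPM of them.

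Light-harvesting transcripts took 0.427% and 0.391% of the counts in WT 2 and WT 3, lower than in the other WT libraries (7.80% or more); both share title stem, medium and genotype with WT 1. The counting difference between the title sets is argued against as the cause, since WT 1 of the same set had a share of 13.6%. Both libraries being a knockout line without PDS1 transcripts, as A2, is argued against by Cre12.g509650, which had 46.6 CPM in the lower of them against an A2 limit of 6.31 CPM. Across 1740 unlisted genes with 1 transcript, the change of WT 2 and 3 against WT 1 went with that of A2 against WT 4 to 6 (Spearman rho = 0.382, Pearson r = 0.459; genes are not independent replicates), which both a mislabelled knockout of another kind, such as E10, and a shared culture state may give. These 2 cannot be told apart here, since the E10 libraries are too shallow to define that line's level of PDS1, and no label describes the state of single cultures.

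By mixture weight the E10 libraries lay nearer WT 1 to 3 than WT 4 to 6. When each was fitted as a mixture of the 6 WT libraries, WT 1 to 3 took at least 94.4% of the weight. The fit included identifiers with several annotated transcripts, at 8.70 to 8.79% of the counts in WT 4 to 6 and at most 0.109% in E10. This counting difference alone can set the split of weight between the title sets, so that split does not measure similarity of the cultures. PDSKO 1 drew 77.5% from WT 1, and PDSKO 2, 3 and 4 drew 0.569%, 0.128% and 0.272% from it. The latter drew 51.3%, 44.3% and 36.0% from WT 2 and 42.6%, 54.4% and 63.0% from WT 3. This split follows the light-harvesting share, at 8.17% in PDSKO 1, 0.207% to 0.649% in PDSKO 2 to 4 and 13.6% in WT 1. Barcode cross-talk from deep libraries as their whole content would leave few identifiers far above the mixture, if each count were drawn independently. In E10, 170 identifiers had 10 or more counts at 10 or more times the mixture's expectation. Simulated mixtures gave 0, and WT libraries thinned to 18000 counts gave 0 to 4 each. PDSKO 1 and 2 held 82 and 66 such identifiers, and PDSKO 3 and 4 held 9 and 14. The simulated and thinned libraries draw each count independently and hold no amplification. A few cross-talk molecules amplified in a low-input library could give such an excess as well, so it does not decide whether cross-talk is the whole content. Of the 170, 0.588% (1 identifier) were in excess in more than 1 E10 library, which few molecules being amplified in low-input libraries may give. Whether cross-talk makes up the content of the E10 libraries cannot be told apart from real similarity of knockout and parental cultures. Both can give a high weight, as can the counting difference, and the residuals do not separate them. The median squared residuals of PDSKO 1 to 4 (2.62, 3.92, 0.939 and 0.916) all exceeded simulated counting noise (0.420 to 0.525). Those of WT libraries thinned to 18000 counts did as well (0.577 to 3.40), a range that PDSKO 2 exceeded. Excess identifiers were not particular to E10: by the same rule A2 had 248, with 3.95% of its counts, and D2 269, with 32.7%. Of these, 15 were in excess in both. A2 drew 84.9% of its weight from WT 4 to 6. D2 drew 33.6% from WT 4 to 6, 38.0% from WT 1 to 3 and 28.4% from an even spread over all identifiers.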

How the results depend on the processing

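Alternatives not planned before the data were examined were the z-score camera test, list shares, TMMwsp scaling, leaving out identifiers with several transcripts, WT 2 and 3, PDSKO 2 and 5 or Cre07.g323800, the 4-group contrasts, their named genes with each library left out, and those of the interaction. The cause of a change was not tested unless the setting itself gives it (fewer libraries or other identifiers tested).

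The count of 0 genes in PDSKO against WT held in 23 of 36 alternatives. It became 164 with RLE factors (151 higher, 13 lower), 4 with no factor, 1257 with no filter (242 higher, 1015 lower), 39 with a mean of at least 50 CPM (39 higher), 413 with DESeq2 (372 higher, 41 lower), 13 with A2 and D2 alone against all WT, 874 with A2 and D2 against WT 4 to 6, 625 for that contrast in the 4-group fit, 1 with E10 summed, 11 without WT 2 and 3, and 483 without shallow libraries, which left 1 PDSKO library. Leaving out each library gave 0 to 632, the 632 without PDSKO 1. The replicate block gave 69 genes (2 higher, 67 lower) and 1 list. Whether library numbers pair the samples was not settled, as same-number correlations ran from -0.0926 to 0.382. Of 6 WT libraries 3 correlated best with their own number.

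PDS1 stayed negative in all 33 alternatives (-12.85 to -1.13, edgeR, DESeq2 or limma adjusted p from 0.0279 to 0.643) and passed in 3: -10.41 with A2 and D2 against WT 4 to 6, -11.91 for that contrast in the 4-group fit and -12.85 without shallow libraries, which leaves 1 PDSKO library. The knockout libraries of these 3 hold 0 counts of it, so these fitted values depend on the prior count and are no fold changes. It was not tested in the 7 libraries of E10 and WT 1 to 3 fitted alone, for too few counts. None of the 45 other named genes passed in the 12-library fit; over 1473 alternative values 70 passed. The sign changed for 14 of them in some alternative, and for 5 with 1 library left out, such as Cre01.g055408 (ACS2, -0.56 to 1.73).

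The count of 0 lists became 5 with fry (all lower), 4 with z-scores (all lower, 0 with an estimated correlation), 2 with RLE and 2 with no factor (both higher), 2 with A2 and D2 against WT 4 to 6, 1 without WT 2 and 3, and 0 to 1 with each library left out. List members adjusted over the list alone numbered 8, of which AGS1 had no other tested member in its list. Exact permutation of shares passed 1 list, overall and within title sets: the 5 photoprotection identifiers, at 0 counts in PDSKO where the WT share would give 3.24, so depth alone limits it.

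E10 against A2 and D2 (387) became 592 with DESeq2, 24 in PDSKO libraries alone and 147 to 646 with each PDSKO library left out (181 without PDSKO 1, 207 without PDSKO 3, 147 without A2, 646 without D2). The parental title sets (91) gave 1516 with no filter, 586 with DESeq2, 1451 fitted alone and 13 to 475 with each WT library left out (475 without WT 1, 13 without WT 5, 21 without WT 6). The interaction (3) gave 0 with RLE, 42 with no filter, 47 without identifiers with several transcripts and 0 to 243 with each library left out.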

Other observations

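The tests in this part were all chosen after the results they address were seen.

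Levels of a pair of named genes set WT 2 and 3 apart from the other WT libraries. Cre04.g215050 (CHYB1), a carotenoid hydroxylase, was at 6.00 and 2.11 CPM in WT 2 and 3 and at 90.5 to 144 CPM in the other WT libraries, with 1 count in A2 and 55.5 CPM in D2. Cre06.g282800 (ICL1), the glyoxylate cycle enzyme used in growth on acetate, was at 8471 and 9104 CPM in WT 2 and 3. It was at 2897 to 5440 CPM in the other WT libraries and 577 CPM in A2. In TMM-scaled CPM, PDSKO 1 to 4 stood at 4858, 2553, 5685 and 5222, A2 at 1532 and D2 at 3151. On that scale WT 2 and 3 stood at 9807 and 10711 and the other WT libraries at 5206 to 6407. The TMM factors of PDSKO 3 and 4 were 1.63 and 1.80, so their unscaled CPM lay higher, near that of WT 2 and 3. In unscaled CPM a high ICL1 level was thus not particular to WT 2 and 3.

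Of identifiers above 10 CPM in the second title set, 342 had 0 counts in all 7 libraries of the first, and 4 the reverse. Of the 342, 338 (98.8%, exact 95% interval 97.0 to 99.7%) have 2 or more annotated transcripts, which is consistent with reads of such identifiers having been discarded in the first set, for instance by mapping to a reference with every transcript in it. A different gene activity in the cultures is argued against, since 0.0657% of identifiers with 1 transcript (4 of 6091) were at 0 in the first set against 58.4% of those with more (338 of 579). No label records a difference in mapping, and the reference used here is of another assembly than the authors'.

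For PDSKO against WT the real count was 0 genes and 0 gene lists, so all 100 splits of the 12 libraries give as many by construction and decide nothing; the highest other split gave 148 genes and the highest other 6 lists. For WT 1 to 3 against WT 4 to 6 the real split gave 1451 genes in the WT libraries alone and the highest other 0, with 1 of the 10 splits as large; 10 splits are too few for a share under 0.05.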
